A study of Zea mays with 6 samples.

How the data were processed

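Messenger RNA abundance was measured by RNA sequencing in 6 leaf libraries of maize (Zea mays): 3 from wild-type plants (WT) and 3 from plants of a line labelled as a knockout of ZmGA20ox3 (KO1). Both groups carry the cultivar label KN5585 and the same label of normal growth, while the growth protocol spells the wild-type line KN5855; which spelling holds, and whether both groups share a background, is not settled here. Leaves were taken at the V8 vegetative stage, per the labels. The labels describe the 3 libraries of each group as biological replicates. Groups and replicate numbers were taken from the sample titles.

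The authors deposited 1 table of TPM values (length-scaled transcript abundance, as a share of each library) for all 6 libraries, with 44320 rows and values rounded to 2 decimals. Each column sums to 1000000 within rounding. RSEM, Bowtie2 and DESeq2 are named in the submitters' processing notes, without versions or roles. The genome build, the annotation release and the filters on reads are not given in the sources used here. TPM divides each gene by its length and rescales each library to a fixed total, so the sequencing depth of the libraries is unknown and no counting interval or detection floor is given. A rise in some transcripts lowers the TPM of all others in the same library.

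Gene identifiers were looked up in a table of 49888 genes of the Zm-B73-REFERENCE-NAM-5.0 assembly from NCBI RefSeq. That table gives names through gene numbers, symbols, accessions and older identifiers, and 0 of the 44320 identifiers matched. The deposited table does not pair its identifiers with names either. Genes are therefore given by identifier, and no gene is named from its identifier. Lists of gibberellin, abscisic acid, jasmonate, photosynthesis, cell wall, defence and other genes, and of markers of other cell types and organs, had been fixed as name patterns before the data were examined. None of these lists was analysed here, and neither was the level of ZmGA20ox3.

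Genes with a TPM of at least 1 in at least 3 of the 6 libraries were tested, which left 20990. KO1 was compared with WT in limma 3.58.1 (R 4.3.3) on log2(TPM + 1), with a variance trend, no covariates and a two-sided test. Benjamini-Hochberg adjustment ran over all tested genes with a threshold of 0.05. Differences are on the log2(TPM + 1) scale, which understates the change of low genes. Folds are ratios of mean TPM and are given for genes with at least 1 TPM in all 6 libraries. Single values per library were compared by an exact two-sided permutation test, whose smallest p with 3 against 3 is 0.1.

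The fixed rule for named genes was the largest rises and falls past the threshold with a mean TPM of at least 5 and a name in the reference. No gene had a name, so the condition on names was dropped and the first 2 in each direction are given by identifier.

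The procedure was tested on simulated data for the KO1 against WT comparison, with 20990 genes drawn at the observed means and spreads. It recovered 22 of 100 genes changed 2-fold and 72 of 100 changed 4-fold, with 9 false calls and 0 calls in the wrong direction. Only these genes were changed, with noise drawn independently for each gene, while 15.7% of tested genes passed in the data. The adjusted threshold was therefore stricter in the simulation, and its recovery and false calls are not estimates for the data. A gene that did not pass may still differ 2-fold.

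Alternatives fixed at the same stage covered the pseudocount, the filter on low values, trimmed-mean scaling (30% of ratios and 5% of levels trimmed at each end, unweighted), quantile normalization, the variance model, library weights, a replicate block and leaving out each library. The replicate numbers were checked for pairing. Deviations from the group mean correlated at -0.01, 0.09 and 0.02 between WT and KO1 libraries of the same number, under the minimum of 0.1, so the numbers were not treated as pairs. Plots were drawn with matplotlib 3.10.9.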

Results

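The series compared leaf transcriptomes of KO1 and wild-type maize. ZmGA20ox3 belongs to the gibberellin 20-oxidases, enzymes of the synthesis of gibberellins, the plant hormones that promote stem elongation. The comparison asks which transcripts differ in leaves of edited plants grown without an imposed stress. The table held 44320 genes, of which 13615 were listed at 0 TPM in all 6 libraries. The level of ZmGA20ox3 itself was not analysed here, because the identifiers could not be paired with gene names, so the knockout was not checked at the transcript level.

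More genes reached 1 TPM in the KO1 libraries. Sequencing depth is unknown and each library total is fixed, so the counts do not show that more genes were expressed in KO1 leaves. Genes at 1 TPM or more numbered 20015 ± 654 in WT (SD, n = 3) and 20933 ± 214 in KO1 (SD, n = 3). Every KO1 library lay above every WT library, and the exact permutation p of 0.1 is the smallest that 3 against 3 can give. The 10 most abundant transcripts of each library took 11.5% ± 0.32 of the TPM total in WT and 10.8% ± 1.57 in KO1 (SD, n = 3 each; exact permutation p = 0.7). The difference in this share was smaller than the spread among KO1 libraries.

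Libraries of the same genotype resembled each other more than libraries of different genotypes. Over the 20990 tested genes, Spearman's rho between WT libraries ran from 0.91 to 0.96 and between KO1 libraries from 0.91 to 0.95. Between a WT and a KO1 library it ran from 0.75 to 0.89. These are correlations across genes, which are not independent replicates. The first principal component held 63.0% of the variance and separated the genotypes, and the second held 14%.

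**Figure D1:**
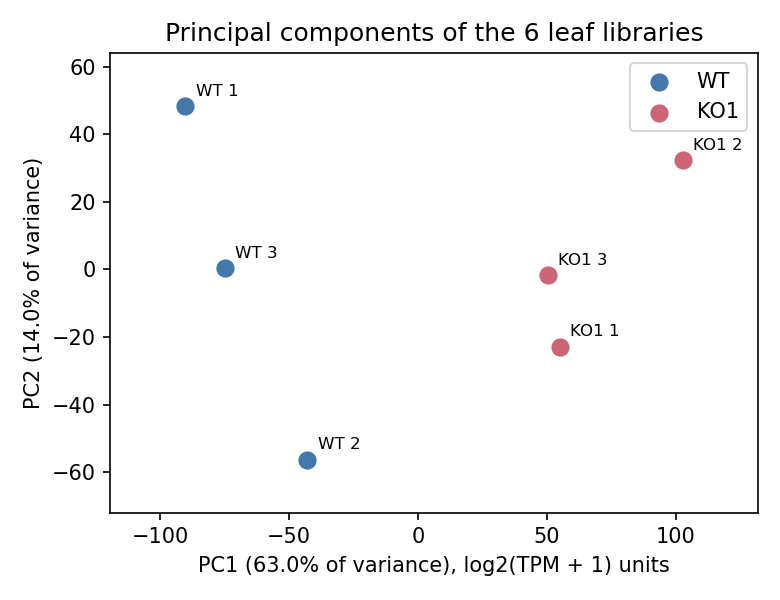
Scores of the 6 libraries on the first 2 principal components of log2(TPM + 1), 1 point per library, coloured by genotype. WT libraries lie between -90.4 and -43.0 on the first component (63.0% of variance) and KO1 libraries between 50.3 and 103.

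KO1 leaves differed from WT leaves in 3301 genes, 15.7% of those tested, at a limma adjusted p under 0.05. Of these, 2071 were higher and 1230 lower in KO1. Large changes were mostly rises: 685 genes rose and 206 fell by at least 4-fold on the log2(TPM + 1) scale. At an unadjusted p under 0.05 there were 7203 genes. The groups did not overlap for 8501 genes, 40.5% of those tested. For a single gene without a difference, the chance of this is 10%. Genes vary together, so the share in a single split can lie far from 10%, and its excess is not a test. The count fell to 1314 without WT replicate 1, 778 without WT replicate 3, 1482 without KO1 replicate 1 and 1856 without KO1 replicate 2, and rose to 6838 (3941 higher, 2897 lower) with library weights. After quantile normalization the calls were 1656 higher and 1738 lower, so the surplus of higher genes did not hold under that scaling, which moved the median log2 difference of all tested genes from 0.05 to -0.09; genes that changed at least 4-fold remained mostly higher, at 559 against 258.

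Among called genes present at 1 TPM or more in all 6 libraries, the typical change was between 2-fold and 4-fold. The 1370 higher genes of this kind rose by a median of 2.68-fold (quartiles 2.06 and 4.03), and 62 of them by at least 10-fold. The 965 lower genes of this kind were lower by a median of 2.36-fold (quartiles 1.93 and 3.15), and 16 of them by at least 10-fold. The largest rise in this set was 87.3-fold and the largest fall 80.2-fold. The called genes were selected on this same difference, which tends to overstate its size. Over all tested genes, the median SD of log2(TPM + 1) within a group was 0.24 in WT and 0.29 in KO1, on another scale than the folds.

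The 2 genes with the largest rise and the 2 with the largest fall were close to on or off by genotype. Ranking called genes by this difference favours genes near 0 TPM in 1 group, so the pattern follows in part from the selection. Zm00001d007569 had 188, 142 and 126 TPM in KO1 replicates 1 to 3, and 0, 0 and 0.15 TPM in WT (limma adjusted p = 4.95e-05). Zm00001d051798 had 60.2, 199 and 87.1 TPM in KO1 and was listed at 0 in each WT library (limma adjusted p = 0.00075). In the other direction, Zm00001d032272 had 187, 124 and 126 TPM in WT and was listed at 0 in each KO1 library (limma adjusted p = 4.95e-05). Zm00001d044558 had 93.3, 71.4 and 93.0 TPM in WT and was likewise listed at 0 in each KO1 library (limma adjusted p = 4.95e-05). No fold is given against a group listed at 0, and in a table without counts such a 0 can also be a failed estimate.

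**Figure D2:**
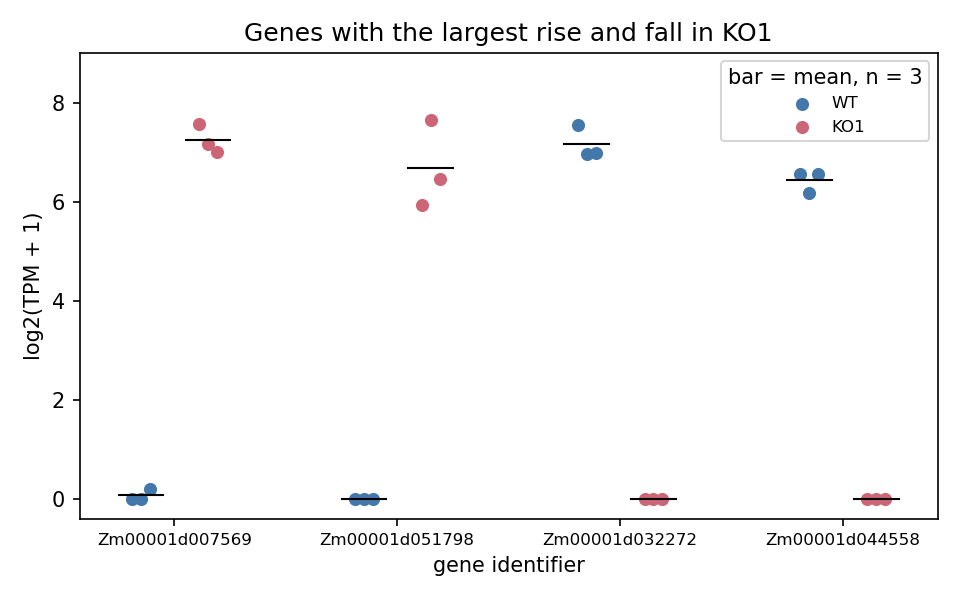
log2(TPM + 1) of the 2 genes with the largest rise and the 2 with the largest fall in KO1, 1 point per library (3 WT, 3 KO1), bars at the group means. For Zm00001d007569, WT libraries had 0, 0 and 0.15 TPM; the other 3 genes were listed at 0 in all libraries of the genotype with the low level.

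A stricter presence or absence by genotype, with 0 TPM in each library of 1 group, held for 130 genes. Zm00001d007569 is not among them, with 0.15 TPM in WT replicate 3. A set of 83 genes was listed at 0 in all 3 WT libraries and reached at least 1 TPM in each KO1 library. The reverse held for 47 genes, listed at 0 in KO1 and present in each WT library. Over the whole table, genes listed at 0 numbered 18359 ± 485 in WT and 17544 ± 157 in KO1 (SD, n = 3 each). How far that accounts for the imbalance of 83 against 47 was not tested. Of the first set 80 passed the limma threshold, and of the second 46, which follows largely from how the sets were selected and is not a separate test. Most were of low abundance where present, with a median of 5.77 TPM in the KO1 set and 4.26 TPM in the WT set, and 23 and 7 of them reached a mean of 10 TPM. With presence set at 5 TPM the count was 34, with 23 present only in KO1 and 11 only in WT, and without WT replicate 2 it was 216.

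Few of the most abundant leaf transcripts passed the threshold as higher in KO1. Of 219 genes with a mean of 500 TPM or more over all 6 libraries, 7 rose, 18 fell and 194 did not pass. Rises were 28% of the calls in this class and 63.0% of the calls among less abundant genes (Fisher's exact test across genes, p = 0.00056). Under trimmed-mean scaling the abundant class held 5 rises and 20 falls, and under quantile normalization 8 and 14; the class differed from the other calls at p = 0.00013 in the first and p = 0.288 in the second (Fisher's exact test). At a limit of 50 TPM the pattern depended on the scaling: rises were 54.0% of calls at or above it and 64.5% below it as deposited, and 53.1% and 47.9% under quantile normalization. Genes are not independent replicates in this test.

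Among the 100 most abundant transcripts, 1 rose, 4 fell and 95 did not pass. The clearest fall in this set was in the transcript ranked 90 by mean abundance, which had 1943, 1694 and 1553 TPM in WT and 570, 384 and 522 TPM in KO1 (limma adjusted p = 0.0069). The single rise past the threshold was in the transcript ranked 95, from 632, 701 and 439 TPM in WT to 1836, 1515 and 1099 TPM in KO1 (limma adjusted p = 0.031). Not passing does not mean no change. The transcript ranked 21 had 213, 3104 and 1764 TPM in WT and 4474, 7073 and 5264 TPM in KO1 (limma adjusted p = 0.132). The transcript ranked 28 had 7273, 3379 and 3461 TPM in WT and 1291, 525 and 1953 TPM in KO1 (limma adjusted p = 0.059). The most abundant transcript of all had 26055, 31601 and 25527 TPM in WT and 42837, 18871 and 26858 TPM in KO1, a difference smaller than the spread between replicates (limma adjusted p = 0.99).

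**Figure D3:**
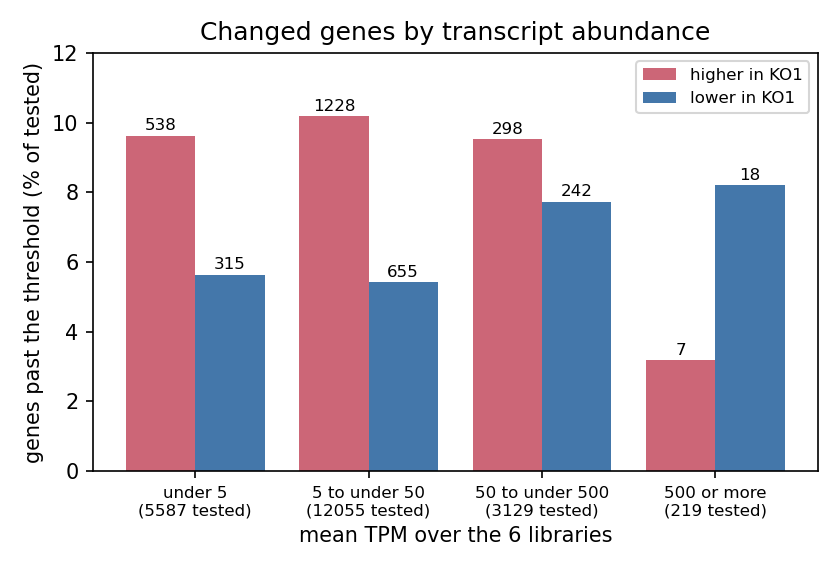
Share of tested genes past the limma threshold (adjusted p under 0.05), by mean TPM over the 6 libraries, with the number of genes above each bar, red for higher and blue for lower in KO1. In TPM as deposited, higher genes outnumber lower ones below 500 TPM (538 against 315, 1228 against 655 and 298 against 242), and the class of 500 TPM or more has 7 higher and 18 lower; under quantile normalization rises were 47.9% of calls below 50 TPM.

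Together the called genes made up a moderate part of the leaf transcript pool. Genes called lower took 9.10%, 7.72% and 8.21% of all TPM in the WT libraries and 3.20%, 2.55% and 3.65% in the KO1 libraries. Genes called higher took 2.55%, 3.18% and 2.61% in WT and 9.54%, 11.6% and 8.77% in KO1. These genes were selected on the same difference, so the shares describe its size and are not a separate test.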

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

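All 4 genes given by identifier kept their direction and stayed past the threshold in all 18 alternative fits, with the highest adjusted p at 0.011 (limma). They were chosen as the largest changes in these same libraries, so this outcome was largely fixed by their selection. The count of 3301 changed genes stayed between 2387 and 3394 under both other pseudocounts, both other filters, both scalings, both other variance models, the 2-fold minimum and single counting of identical rows. It was 6838 with library weights, where WT replicate 3 received a weight of 8.53 and no other library more than 1.07. The count of non-overlapping genes, the smallest p of an exact permutation test without adjustment, was 8501. Leaving out each library in turn gave 778 to 2929 genes, and leaving out WT replicate 1 and KO1 replicate 2 together, an alternative chosen after seeing the data, gave 1016. Without WT replicate 3, 771 of the 778 genes were among the 3301 with the same direction, and without WT replicate 2, 2320 of the 2929; the cause of the range was not tested. In none of these settings was a gene called in the opposite direction. The share of higher calls was 62.7% as reported, 58.4% under trimmed-mean scaling, 48.8% under quantile normalization and 70.5% without WT replicate 2. With a replicate block the count was 2806; the replicate numbers share only a number, and only the libraries numbered 2 correlated best with each other. The count of 130 genes present in only 1 genotype was 34 with presence at 5 TPM, 159 with at most 0.1 TPM in place of 0, and 166 to 216 when each library was left out in turn, all chosen after seeing the data. Leaving out a library loosens the criterion by construction. The alternatives for the gene lists and for ZmGA20ox3 were not run, since no list could be paired with identifiers. Depth is unknown, so it is open how far low levels limit the calls.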

Other observations

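In the paragraphs below, the test of the spread within groups was set out before its result was seen. The tests of the gene class by identifier form, of the splits of the libraries, of identifier neighbourhood and of compensating neighbours were chosen after the result was seen, and the criterion for the scaling test was tightened after it.

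The table holds 174 genes whose identifiers have another form than the 44146 others (GRMZM5G in place of Zm00001d). Their TPM summed to 149 ± 43.1 in WT and 274 ± 51.7 in KO1 (SD, n = 3 each), with every KO1 library above every WT library (exact permutation p = 0.1, the smallest possible). Of the 35 tested, 1 passed over all genes as higher in KO1 and 34 did not; adjusted over the list alone, 0 passed. Their median difference was 0.64 on the log2(TPM + 1) scale. Against all other genes the limma camera test gave p = 0.009 with a preset correlation of 0.01, and p = 0.267 with an estimated correlation of 0.13. What these genes encode was not analysed here.

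Of rows above 0, 2270 share all 6 values with another row, and 70 of these rows, in 33 sets, were tested. Copies that a counter cannot tell apart and low values that coincide after rounding to 2 decimals both give equal rows, and the 2 were not separated over all rows. The rows ranked 7 and 8 by mean abundance had 5510 TPM each in WT replicate 1, and those ranked 55 and 56 had 270 TPM each. These are too abundant to be low values that coincide. The tested rows of this kind hold 14 of the 3301 calls, so they bear little on the count.

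The real split of the 6 libraries called 3301 genes and the highest of the other 9 splits called 2. Each of the other splits mixes the genotypes, so a genotype difference widens the spread within its groups and keeps its count low. The gap between these counts is therefore not a measure of chance. Of the 10 splits, 1 gave a count as large, the real one, and 10 splits are too few for a share under 0.05.

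The real split gave 130 genes present in only 1 genotype and the highest other split 9. Here too, mixing the genotypes keeps the count of the other splits low. Of the 10 splits, 1 was as large, too few splits for a share under 0.05. Both genotypes carry the cultivar label KN5585 while the growth protocol spells the wild-type line KN5855, so whether the plants shared a genetic background is open, and a candidate explanation is that they differ in blocks of genome sequence beyond the edited gene. If identifier numbers follow gene order, such blocks would bring these genes close together, and after identical rows were counted once the 129 genes formed 86 pairs lying 11 to 200 numbers apart, against a median of 60 and a 95th percentile of 74 in 10000 random draws of expressed genes. The excess was uneven, with 8 pairs against a random 95th percentile of 7 at 1 to 10 numbers, 12 against a median of 13 at 11 to 50, 74 against a median of 48 at 51 to 200 (permutation p from random draws = 0.00050, the smallest 2000 draws can give), and 236 against a median of 246 beyond that, up to 1000. With the densest span of 400 numbers left out of the set and of each draw, 65 pairs remained against a median of 53 and a 95th percentile of 65 (permutation p from random draws = 0.057), so blocks stay open and are not shown.

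Reads moving between neighbouring copies were tested through opposite changes within 5 numbers at least 0.5 times as large, found for 79 of the 129 genes against a median of 91 for random sets. The set showed no excess, and most random genes met the criterion as well, so the test could not decide. Copies elsewhere in the genome were not searched either. Movement of reads between copies therefore remains open, as does an effect of the edited gene on these transcripts.

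The surplus of higher over lower calls may come in part from the composition of the libraries, since TPM fixes each library's total. The 2 scalings disagreed: the share of higher calls was 62.7% as reported, 58.4% under trimmed-mean scaling, which centred the median difference, and 48.8% under quantile normalization, which forces equal distributions and moved that median to -0.09. The balance over all calls therefore depends on the method, and a broader set of transcripts in KO1 leaves stays open. Among genes changed at least 4-fold the surplus held under all 3 scalings, at 685 against 206, 642 against 221 and 559 against 258.

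The difference between genotypes may lie partly along a gradient that also varies within genotypes, such as leaf position or time of harvest, which the labels do not give per library (the V8 stage is given for all). Across the 20990 genes, WT replicate 3 minus WT replicate 2 correlated at r = -0.40 with KO1 minus the held-out WT replicate 1, and KO1 replicate 3 minus KO1 replicate 2 at r = -0.28 with the held-out KO1 replicate 1 minus WT, where independent replicate noise predicts values near 0. The smaller of these sizes, 0.277, missed the 0.3 that had been set for both groups. With WT replicate 2 or KO1 replicate 2 as the held-out library, the difference of the other pair gave -0.08 and -0.005 over all tested genes, and -0.10 and -0.13 over genes at 1 TPM or more in all libraries. With replicate 3 held out, replicate 2 minus replicate 1 gave 0.29 in WT and 0.27 in KO1 over all tested genes. Over genes at 1 TPM or more in all libraries these were 0.29 and 0.20. With 3 libraries per genotype, a gradient in sampling and an effect of genotype on the same genes cannot be told apart.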
